A study of Homo sapiens with 15 samples.

How the data were processed

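Transcript levels of MHCC-97H, an established human hepatocellular carcinoma cell line, were measured by RNA sequencing in 15 libraries. Per the labels, 3 libraries came from each of 5 groups: cells in a 2D model, cells in a 3D model, an animal model, untreated cells in the 3D model and heat-treated cells in the 3D model. The series design describes the last pair of groups as a separate round of sequencing, so 9 libraries form a first experiment and 6 a second. Temperature, duration of heating, time of collection and the host animal are not given in the labels. Nor do the labels say that replicates are separate cultures or animals, so every p-value measures the spread between these libraries.

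Per the labels' protocols, RNA was extracted with a spin-column kit, mRNA was fragmented and primed with random hexamers, and short single-end reads were made by DNA nanoball sequencing. The protocol describes no step that marks the strand. HISAT2 and the genome build hg19 are named in the submitters' processing notes, without a version. The counting program, the gene annotation, the strand setting and any removal of host reads are not stated. The deposited values are raw read counts per gene symbol, 1 column per library, with whole numbers and a different total in each column. The table has 19143 rows, of which 1443 hold 0 in every library. In 27 rows the gene symbol had been turned into a calendar date, and these hold 0.168% of all counts; they were kept under the date label and never named. Total counts were 12605539 to 18634295 per library. No molecular identifiers are mentioned, so intervals and floors cover counting error only.

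Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed edgeR's filterByExpr by group, library sizes were scaled by TMM, and a robust quasi-likelihood model with group as its only term was fitted to the 9 libraries of the first experiment and apart from them to the 6 of the second. The 4 comparisons were 3D against 2D, animal against 2D, animal against 3D, and heat against control in 3D. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. All adjusted p-values come from this edgeR test unless another tool is named. Levels are in CPM, computed by edgeR's cpm function from the deposited counts with TMM factors, and are given as mean ± SD over n = 3 libraries. A floor of 3 counts per library, on the same scale, bounds a fold where every library of a group has 0 reads, and where a group has 1 to 3 reads in all, the ratio of pooled reads has an exact Clopper-Pearson 95% interval.

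Before the data were examined, 31 gene lists were fixed, 25 for pathways and 6 for markers of other cell types. Of their 544 entries, 541 matched a row, 3 through an older symbol; OAS1, PECAM1 and MRC1 matched none and are not analysed here. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The fry test, which asks whether a list's genes move one way on balance, was run beside it. Member counts are over all genes tested, followed where stated by counts adjusted over the list alone.

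The genes named were chosen by a rule fixed before the data were examined. It takes the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM whose groups do not overlap, leaving out pseudogenes, antisense and unnamed loci. It adds SP1, IL4I1 and AHR, the 3 genes of the series title, and 2 to 4 members with the smallest adjusted p for each list that passed and for the chaperone, AHR target and tryptophan lists. It also takes the 5 genes per direction with the largest shared change in the 3D and animal libraries. Other genes named below were chosen after their values were seen and are introduced as such. Transcript GC content and length were those of each gene's longest protein-coding transcript in GENCODE 29, matched by symbol for 99.1% of the tested genes. No coordinates are given, since its build differs from hg19. It was also used for chromosome names and for the overlap of IL4I1 with NUP62.

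Alternatives fixed beforehand were DESeq2 1.42.0 in place of edgeR, median-ratio and upper-quartile scaling, no filter and a stricter filter (at least 10 reads in every library of a group), replicate number as a block, only the 2 groups compared, a fold threshold of 2, removal of the cell type markers, and, for gene and list counts, named genes and shared genes, leaving out each replicate. After the data had been seen, 4 more were added: an offset for each library's trend with GC content and length (splines with 5 degrees of freedom), a fit without 3D replicates 1 and 2, correlations and list counts without those and heat replicate 1, and correlations with each replicate left out. With 3D replicate 3 alone, that library is assumed to vary like the other groups.

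The methods were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes per comparison. For 3D against 2D (12627 genes), edgeR recovered 59% of 4-fold and 2% of 2-fold changes with 9 false calls, and DESeq2 recovered 88% and 30% with 53. For heat against control (12431 genes), edgeR recovered 28% and 1% with 2 false calls, and DESeq2 80% and 13% with 43. For animal against 2D (12654 genes) edgeR recovered 59% and 2%, and for animal against 3D (12643 genes) 71% and 4%. The GC and length trends of the real libraries were then laid over the simulated counts. The dispersions came from libraries that already carry these trends, so their spread may be counted again in the values that follow. For 3D against 2D (12648 genes) the uncorrected edgeR fit, as used in the main analysis, recovered 44% of 4-fold changes with 42 false calls, and the corrected fit 67% with 4. For animal against 2D (12649 genes) they recovered 0% with 0 false calls and 59% with 3. For animal against 3D (12657 genes) they recovered 62% with 390 and 62% with 3. For heat against control (12401 genes) they recovered 0% with 0 and 20% with 4. In the simulation of lists (12729 genes, 3D against 2D), camera called the raised list and 0 of 20 unchanged lists.

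Replicates were not duplicates of one another: the scatter between replicates of a group was 2.52 to 521 times that expected from counting alone. Residuals of libraries with the same number did not pair across groups (r across genes from -0.187 to 0.125), so the unblocked fit was kept as the main one.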

Results

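RNA sequencing read counts of MHCC-97H, an established hepatocellular carcinoma cell line, were compared between culture models and between heat-treated and untreated cells. The first experiment holds 3 libraries each from a 2D model, a 3D model and an animal model. The second holds 3 untreated and 3 heat-treated libraries from the 3D model. Total counts were 17789899 to 17879280 in the 2D libraries, 16632141 to 18634295 in the 3D libraries and 12605539 to 14538432 in the animal libraries. They were 16789095 to 16963026 in the 3D controls and 15991686 to 16112893 in the heated libraries. Between 14218 and 15666 genes had at least 1 read per library.

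In 3 libraries, 3D replicates 1 and 2 and heat replicate 1, levels followed transcript composition. Across genes, their departure from the 2D libraries had rank correlations of 0.593 to 0.797 with transcript GC content, against -0.184 to 0.226 in the other 12 libraries. With transcript length the values were -0.457 to -0.414 against -0.136 to 0.244. FTL, the ferritin light chain, singled out after its values were seen, took 3.04 to 4.57% of their counts against 0.778 to 1.33% elsewhere, and mitochondrial transcripts took 1.31 to 4.57% against 4.52 to 11.3%. The TMM factors were 0.649 to 0.769 against 0.969 to 1.28. The mitochondrial share was also lower in heat replicates 2 and 3, at 4.93 and 4.52%, than in the 3D controls, at 7.99 to 9.59%. Lists described below in comparisons that use these libraries therefore carry a median from a fit without 3D replicates 1 and 2, or without heat replicate 1, and in places one after a correction for GC content and length. These medians give a size only and do not say whether a list would still pass camera.

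**Figure D1:**
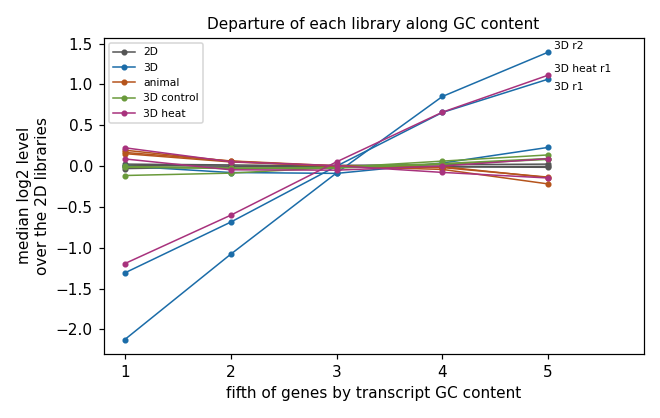
Median log2 level over the 2D libraries (y axis) of genes in 5 classes of transcript GC content (x axis, low to high), 1 line per library, coloured by group. The lowest class lies at -1.31, -2.12 and -1.19 in 3D replicates 1 and 2 and heat replicate 1, and between -0.11 and 0.22 in the other 12 libraries.

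The series title names the transcription factor SP1, the secreted amino acid oxidase IL4I1 and the ligand-activated receptor AHR. IL4I1 was 26.1-fold higher in 3D than in 2D, at 10.9 ± 6.50 CPM against 0.410 ± 0.160 (n = 3; adjusted p = 0.00116 in edgeR), and it was called under all 16 alternatives. Its log2 fold change was 3.73 without 3D replicates 1 and 2, against 4.71 with them. In the animal libraries IL4I1 lay at 1.98 ± 0.451 CPM, 4.76-fold above 2D (adjusted p = 0.0252), a call that ended on leaving out any 2D library, animal replicate 1 or animal replicate 3 (adjusted p 0.0588 to 0.113). Against 3D, IL4I1 was 5.49-fold lower in the animal libraries (adjusted p = 0.00481). With heat it measured 10.9 ± 2.69 CPM against 0.974 ± 0.111 in the controls, higher in 3 of 3 libraries, with an adjusted p of 0.0604 in the main edgeR fit. That p was 0.00437 without heat replicate 1, 0.0257 without heat replicate 2, 0.0117 after the GC and length correction, and at most 0.461 over all alternatives. IL4I1 overlaps NUP62 on the same strand in GENCODE, so part of its reads are uncertain. With the 15 libraries scaled together, NUP62 measured 165 ± 4.26 CPM in 2D, 157 ± 63.2 in 3D and 129 ± 5.73 in animal libraries. It measured 135 ± 7.85 in the 3D controls and 208 ± 44.7 with heat.

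AHR was 2.79-fold lower in 3D than in 2D, at 40.4 ± 27.7 against 113 ± 6.66 CPM (adjusted p = 0.0290). The AHR call was kept under 10 of 16 alternatives. It ended, among other settings, after the GC and length correction (log2 fold change -0.41, adjusted p = 0.0767) and on leaving out any 2D library or 3D replicate 1 (adjusted p up to 0.106). It held without 3D replicates 1 and 2 together, at a log2 fold change of -0.67 (adjusted p = 0.0181) against -1.48 with them. AHR was 3.28-fold higher in the animal libraries than in 3D (133 ± 21.6 CPM, adjusted p = 0.0140), again not after the correction (adjusted p = 0.0650) or without 3D replicate 1 (0.0602). That call also held without both, at 0.88 (adjusted p = 0.00581) against 1.71. Its values with heat were 119 ± 62.9 against 95.1 ± 8.83 CPM (adjusted p = 0.703), and 0.0362 without heat replicate 1. SP1 measured 148 ± 2.99, 138 ± 48.4 and 151 ± 14.8 CPM in 2D, 3D and animal libraries, with adjusted p-values of 0.773, 0.957 and 0.679 for 3D against 2D, animal against 2D and animal against 3D. With the correction SP1 had a log2 fold change of 0.42 in 3D against 2D (adjusted p = 0.0162), the opposite sign of the -0.10 without it, and 0.37 without 3D replicates 1 and 2. In animal against 3D its sign turned too, to -0.36 with the correction (adjusted p = 0.0256) and -0.36 without 3D replicates 1 and 2. With heat, SP1 was at 171 ± 39.9 against 189 ± 4.34 CPM (adjusted p = 0.779).

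**Figure D2:**
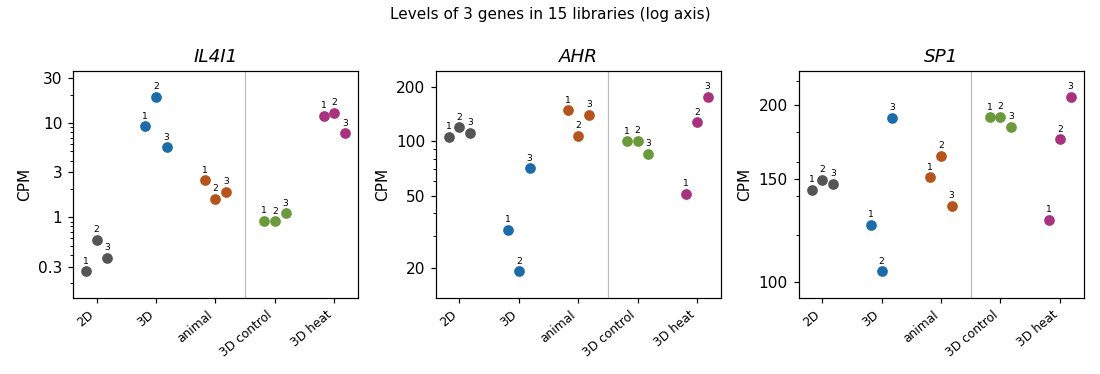
CPM (log axis) of IL4I1, AHR and SP1 in each of 15 libraries, scaled together; points are libraries, numbers are replicates, and the vertical line parts the 2 experiments. IL4I1 lies between 0.27 and 0.58 in the 2D libraries, 5.53 and 18.9 in the 3D libraries, 0.907 and 1.10 in the 3D controls and 7.76 and 12.8 after heat.

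The comparison of 3D with 2D asks what the 3D environment changes, and uses the 3D libraries of the first experiment only. In the 3D controls of the second experiment, 123 genes were higher and 1 lower than in 2D (edgeR over the 15 libraries, 13227 genes). Batch and group cannot be told apart there, so the changes below are those of the first experiment's 3D libraries. Genes of the hypoxia response and glycolysis were higher in 3D. Of 22 tested hypoxia genes, 15 were higher and 0 lower (17 higher adjusted over the list alone, median log2 fold change 1.67, 2.17 without 3D replicates 1 and 2). Among them, ANGPTL4, a secreted lipase inhibitor, rose to 705 ± 155 CPM from 32.0 ± 4.15, CA9, a carbonic anhydrase, 20.2-fold to 374 ± 101, PFKFB4, a regulator of glycolysis, 14.5-fold to 185 ± 30.9, and the stress gene NDRG1 10.8-fold. Of 17 glycolysis genes, 14 were higher (14 adjusted over the list alone, median 1.59, 0.93 without the 2 libraries). The glycolytic enzymes ALDOC and ENO2 were 13.5-fold and 8.32-fold higher, and the lactate exporter SLC16A3 4.12-fold. Camera adjusted p-values were 1.18e-10 and 2.24e-09, and with an estimated correlation the adjusted p was 0.329 and 0.174.

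Cell cycle genes were lower in 3D. Of 20 G2 and M phase genes, 13 were lower and 0 higher (14 adjusted over the list alone, median -1.12, -1.41 without 3D replicates 1 and 2), and of 20 replication genes 11 were lower (13 adjusted over the list alone, median -1.05, -1.65 without them). The proliferation marker MKI67 was 4.07-fold lower, at 91.4 ± 12.6 against 372 ± 13.6 CPM, the spindle checkpoint kinase BUB1B 3.86-fold, cyclin CCNA2 3.86-fold and the replication clamp PCNA 2.60-fold. Camera gave adjusted p = 2.23e-08 and 4.92e-07, against an adjusted p of 0.0840 and 0.346 with an estimated correlation. Of 25 heat shock chaperones, 9 were lower and 1 higher (10 lower adjusted over the list alone, median -0.32, -1.09 without the 2 libraries; camera adjusted p = 0.00212, 0.510 with an estimated correlation). HSPH1 was 5.04-fold lower, HSPD1 2.96-fold, HSPA4 2.91-fold and DNAJA1 2.49-fold.

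Inflammatory, interferon and sterol genes were higher in 3D. Of 18 NF-kB and inflammatory genes 13 were higher (13 adjusted over the list alone, median 1.43, 1.60 without 3D replicates 1 and 2). The chemokine CCL20 was 7.08-fold and the adhesion molecule ICAM1 4.24-fold higher. Of 21 interferon response genes 13 were higher (15 adjusted over the list alone, with 1 lower; median 1.5, 1.30 without the 2 libraries), with the transcription factor IRF7 at 4.34-fold and HLA-C, a class I antigen-presenting molecule with near-identical relatives, at 3.43-fold. Of 23 cholesterol synthesis genes 13 were higher (13 adjusted over the list alone, median 1.07, 0.99 without them). The reductase DHCR7 was 4.33-fold and the decarboxylase MVD 4.56-fold higher. Camera adjusted p-values were 3.07e-07, 1.04e-05 and 0.000109, and with an estimated correlation the adjusted p was 0.0542, 0.0542 and 0.174. After the GC and length correction the medians of these lists were 1.30, 0.81 and 0.69.

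Further lists passed camera. Of 28 ribosomal protein genes 25 were higher (25 adjusted over the list alone), with a median of 1.34 in the main fit, 0.47 without 3D replicates 1 and 2 and 0.33 after correction, and 12 higher and 2 lower then (adjusted p = 3.76e-08, 0.449 with an estimated correlation). RPS27 rose 2.99-fold, whereas RPLP2 had a log2 fold change of 1.54 before and 0.04 after the correction, and 0.67 without 3D replicates 1 and 2 (adjusted p = 0.00117). Of 22 oxidative phosphorylation genes 9 were higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 0.90, and -0.09 without the 2 libraries (adjusted p = 0.00896, 0.642 with an estimated correlation). COX7C was 2.59-fold higher and NDUFS1 1.81-fold lower, both subunits of the respiratory chain. NDUFS1 had a log2 fold change of 0.15 after the correction (adjusted p = 0.716) and -0.85 without 3D replicates 1 and 2 (adjusted p = 0.00113), against -0.86 in the main fit. Its 3D libraries measured 42.5, 47.2 and 45.7 CPM, so the fall is also seen in replicate 3, which is not among the 3 libraries that stand apart. COX7C had 1.96 after the correction and 0.63 without the 2 libraries. Of 16 YAP and TEAD target genes 6 were lower and 1 higher (6 and 1 adjusted over the list alone, median -0.40, -0.29 without the 2 libraries; adjusted p = 0.0434, 0.510 with an estimated correlation). The YAP list did not pass camera after the GC and length correction (adjusted p = 0.126) or with replicate number as a block (adjusted p = 0.0585). TGFB2, a growth factor, was 4.35-fold lower and the receptor kinase AXL 2.55-fold higher. Of 9 macrophage and leukocyte markers 4 were higher (5 adjusted over the list alone, median 1.59, or 1.96 with the member at 0 reads in a group set at its bound, and 1.38 without the 2 libraries; adjusted p = 0.0174, 0.174 with an estimated correlation), among them the lysosomal protein CD68 at 427 ± 42.2 against 101 ± 2.90 CPM.

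The largest rises in 3D were in DUOXA2 (23.9 ± 11.2 against 0.0714 ± 0.0310 CPM) and DUOX2 (93.4-fold), the maturation factor and the enzyme of a hydrogen peroxide-producing oxidase, in the iron-binding protein LCN2 (57.0-fold), REG4 (55.7-fold), the mucosal peptide TFF1 (39.7-fold) and PDZK1IP1 (32.0-fold). Without 3D replicates 1 and 2 the log2 fold changes of DUOXA2, DUOX2, LCN2, REG4, TFF1 and PDZK1IP1 were 7.92, 6.79, 4.05, 3.72, 4.42 and 4.27, against 8.24, 6.55, 5.83, 5.80, 5.31 and 5.0 with them. The largest falls were in ESCO2 (9.62-fold), a cohesin acetyltransferase, FAM111B (8.47-fold), DDIAS (7.87-fold), the co-chaperone FKBP5 (7.49-fold), the microtubule protein MAP2 (7.29-fold) and KLHL4 (7.06-fold). Leaving out the same 2 libraries, the log2 fold changes of ESCO2, FAM111B, DDIAS, FKBP5, MAP2 and KLHL4 were -2.19, -2.03, -2.48, -3.33, -2.50 and -2.0, against -3.27, -3.08, -2.98, -2.90, -2.87 and -2.82 with them, so the order of sizes rests on those libraries. Without 3D replicate 1 the adjusted p of ESCO2 was 0.0539 and that of FAM111B 0.0536. AHR targets did not pass as a list (median 0.51, 0.45 without 3D replicates 1 and 2, camera adjusted p = 0.553; 2 of 10 higher and 1 lower, and the same numbers adjusted over the list alone). The xenobiotic-metabolising enzyme CYP1A1 rose 7.64-fold to 16.4 ± 9.10 CPM, the aldehyde dehydrogenase ALDH3A1 was 3.54-fold higher (adjusted p = 0.0108, 0.0745 without 3D replicates 1 and 2 and 0.0636 after the correction), and EREG was 4.31-fold lower (adjusted p = 0.0241, at most 0.0914 over the alternatives, of which 11 of 16 kept the call). The log2 fold change of EREG was -1.17 without 3D replicates 1 and 2, against -2.11 with them. Tryptophan catabolism genes had a median of -0.24, or -0.07 with the member at 0 reads set at its bound (adjusted p = 0.930; 4 of 16 higher and 3 lower, also adjusted over the list alone). Their median was -0.08 without 3D replicates 1 and 2. KYNU, which cleaves kynurenines, was 1.82-fold lower, at 53.1, 51.0 and 43.2 CPM in 3D replicates 1, 2 and 3 against 89.5 ± 1.63 in 2D. Its log2 fold change was 0.82 after the correction (adjusted p = 0.232) and -1.06 without 3D replicates 1 and 2 (adjusted p = 0.00205), and 15 of 16 alternatives kept the call.

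In all, 2586 genes were higher and 1661 lower in 3D among 12925 tested, and the CPM of the groups did not overlap for 50.2% of genes, where chance gives 10%. The counts were 1764 and 2700 after the correction, with 1186 and 1208 genes shared, 3111 and 3205 without 3D replicates 1 and 2, 4560 and 4933 without 3D replicate 3, 1618 and 798 without 3D replicate 1, and between 1132 and 1221 and between 663 and 729 on leaving out any 2D library. The other 17 lists tested did not pass camera, with adjusted p-values from 0.0613 to 0.930. Among them, the median, the mean and the direction in camera differed in sign for the tryptophan, fatty acid synthesis, mesenchymal, NRF2 target and fibroblast lists. NRF2 targets had a median of 0.44 in the main fit, -0.34 after the correction and -0.73 without 3D replicates 1 and 2. In the main fit 3 of 19 were higher and 6 lower, with a mean of -0.04 and a camera direction of down. The positive sign of the median thus rests on those 2 libraries, while the mean and the camera direction point down with them too. The red blood cell list and the fat and muscle list had fewer than 3 tested members and were not tested.

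The comparison of the animal model with 2D asks how cells in an animal differ from cells on plastic. Removal of host reads is not stated, so rises in the animal libraries may include reads from host cells. For the hepatocyte, inflammatory and interferon genes, and for the largest rises below, a share of host reads was not tested. Their rises therefore cannot be assigned to the cell line alone. Hepatocyte genes were higher in the animal libraries, 12 of 21 tested against 1 lower (13 and 2 adjusted over the list alone, median 2.21). The iron carrier TF was 222-fold higher, at 144 ± 83.2 against 0.643 ± 0.237 CPM, albumin (ALB) 69.1-fold at 165 ± 106 against 2.37 ± 0.234, AMBP 30.7-fold and the urea cycle enzyme CPS1 27.4-fold. NF-kB and inflammatory genes were higher in 12 of 18 (15 adjusted over the list alone, median 1.63), with the chemokines CXCL5 at 24.3-fold, CXCL8 at 11.8-fold and CCL20 at 8.36-fold. Interferon response genes were higher in 10 of 21 (12 adjusted over the list alone, median 1.04), with IFI27 at 31.9-fold and IFI6 at 5.96-fold. Camera adjusted p-values were 9.73e-10, 1.55e-12 and 3.20e-06, and each of these lists passed with an estimated correlation (adjusted p = 0.0106).

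Markers of other cell types moved with the animal libraries. Of 9 macrophage and leukocyte markers 6 were higher (7 adjusted over the list alone, median 2.66, camera adjusted p = 2.16e-07, 0.0106 with an estimated correlation). The antigen-presentation chaperone CD74 measured 21.8 ± 2.92 against 1.62 ± 0.334 CPM, and the integrin ITGAM 11.6 ± 0.866 against 3.42 ± 0.634. Of 13 fibroblast and pericyte markers 7 were higher and 1 lower (7 and 1 adjusted over the list alone, median 1.77, adjusted p = 0.000116, 0.155 with an estimated correlation). The collagens COL1A1 and COL3A1 were 34.6-fold and 49.8-fold higher, at 142 ± 95.4 and 36.8 ± 26.1 CPM. Of 9 mesenchymal transition genes 5 were higher (5 adjusted over the list alone, with 1 lower; median 1.10, adjusted p = 0.0361, 0.405 with an estimated correlation), led by the matrix protein SPARC at 33.7-fold. Leaving the cell type markers out of the tested genes gave 988 higher and 546 lower genes.

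Hypoxia genes were higher in 6 of 22 (6 adjusted over the list alone, median 0.91, camera adjusted p = 7.19e-05, 0.414 with an estimated correlation), with the oxygen sensor EGLN3 at 20.1-fold and CA9 at 8.97-fold. Of 10 AHR target genes 2 were lower and 1 higher (6 and 1 adjusted over the list alone, median -1.08, adjusted p = 0.00307, 0.155 with an estimated correlation). CYP1B1, a hormone- and xenobiotic-metabolising enzyme, was 37.0-fold lower at 2.60 ± 0.492 against 96.2 ± 7.60 CPM. CYP1A1 had 3 reads over the animal libraries against 120 over the 2D libraries, a ratio of 34.0 (95% interval 11.4 to 167; adjusted p = 0.00234), and UGT1A6, whose reads can be shared within its gene cluster, was 8.53-fold higher. Tryptophan catabolism genes were higher in 3 of 16 (3 adjusted over the list alone, median 0.31, adjusted p = 0.138), with the dioxygenase TDO2 at 21.3 ± 5.25 against 6.53 ± 0.855 CPM (adjusted p = 0.0303, at most 0.134 over the alternatives). Chaperones were higher in 2 of 25 (2 adjusted over the list alone, median 0.05, adjusted p = 0.775), with HSPA6 at 23.1 ± 18.5 against 1.32 ± 0.258 CPM (adjusted p = 0.0114, at most 0.0628 over the alternatives).

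Lower lists in the animal libraries were NRF2 targets (2 of 19 lower, 7 adjusted over the list alone, median -0.71, adjusted p = 3.92e-05, 0.270 with an estimated correlation), G2 and M phase (3 of 20, 10 adjusted over the list alone, median -0.57, adjusted p = 0.000340, 0.155 with an estimated correlation) and YAP and TEAD targets (6 of 16, 7 adjusted over the list alone, median -0.68, adjusted p = 0.00163, 0.288 with an estimated correlation). The antioxidant enzymes SRXN1 and TXNRD1 fell 2.67-fold and 1.96-fold, the mitotic kinase AURKA 2.02-fold, and the YAP targets FJX1 and MYOF 5.52-fold and 2.41-fold. Replication genes (1 of 20 lower, 0 adjusted over the list alone, median -0.46, adjusted p = 0.00725, 0.469 with an estimated correlation), fatty acid synthesis genes (2 of 13, 2 adjusted over the list alone, median -0.25, adjusted p = 0.0204, 0.387 with an estimated correlation) and immediate early genes (2 of 15 lower and 1 higher, 4 and 1 adjusted over the list alone, median -0.41, adjusted p = 0.0277, 0.414 with an estimated correlation) passed as well. ACSL1 and SREBF1, an acyl-CoA ligase and the regulator of lipid synthesis, fell 2.94-fold and 2.55-fold, and the growth-response factor EGR1 fell 3.52-fold.

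The largest rises in the animal libraries were in VCAM1, a vascular adhesion molecule with 0 reads in every 2D library (at least 202-fold higher, against 3 counts per library), ACSS3 and ADH1C, each with 3 reads over the 2D libraries (ratios of 451 and 433, 95% intervals 154 to 2189 and 148 to 2101), the immunoglobulin transporter PIGR (36.4 ± 12.5 against 0.142 ± 0.153 CPM), TF, and ITM2A (210-fold). The largest falls were in the Hedgehog transcription factor GLI2 (64.0-fold), the elongation factor EEF1A2 (38.0-fold), ENPP2 (37.0-fold), CYP1B1, the creatine synthesis enzyme GAMT (26.6-fold) and PREX1 (24.5-fold). In all, 1006 genes were higher and 549 lower among 12925, and 66.4% did not overlap. The main fit pools its spread over all 9 libraries, the 3D ones included, though these take no part in this comparison. The counts were 3751 and 3538 with only the 2D and animal libraries in the fit, 1707 and 2332 after the correction, between 446 and 484 and between 199 and 208 on leaving out any 2D library, and 627 and 217 without animal replicate 1. Without animal replicate 3, 249 genes were lower. The other 15 lists had camera adjusted p-values from 0.0523 to 0.940. For chaperones, glycolysis, cholesterol synthesis, fatty acid oxidation and integrins, the median, the mean and the direction in camera differed in sign.

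**Figure D3:**
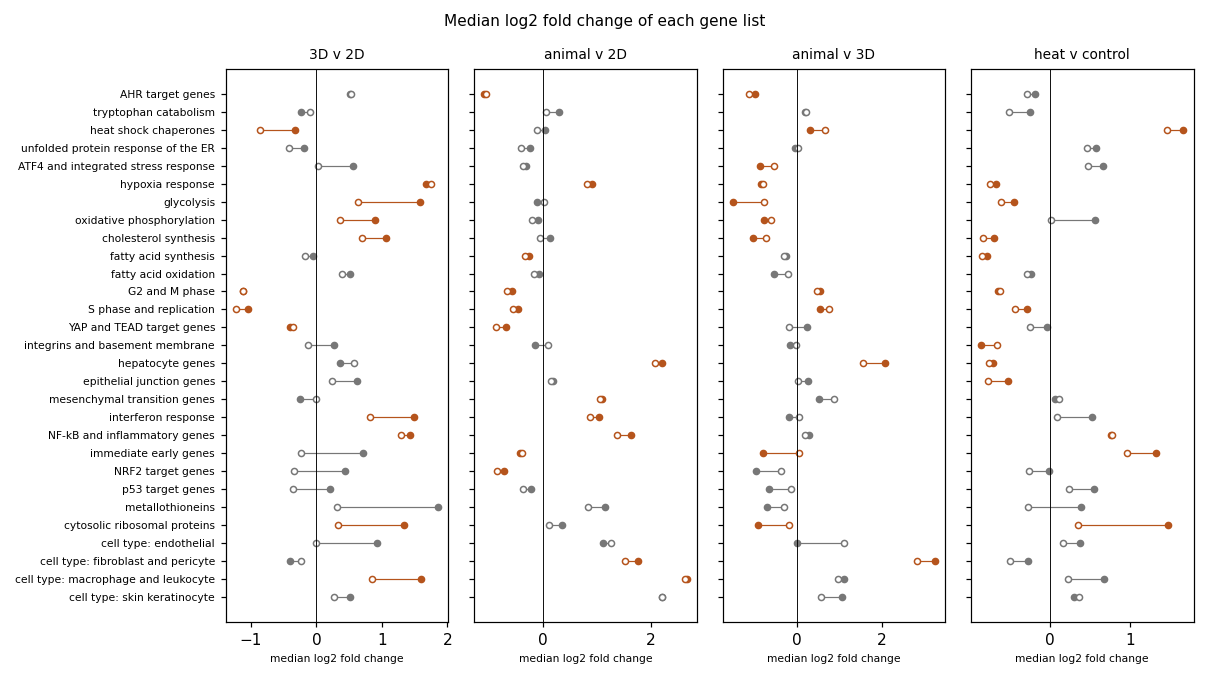
Median log2 fold change (x axis) of each gene list in the 4 comparisons; filled points are the main fit, open points the fit corrected for GC content and length, and orange marks a camera adjusted p below 0.05 in the main fit. Ribosomal proteins in 3D against 2D move from 1.34 to 0.33, and hepatocyte genes in animal against 2D lie at 2.21 and 2.09.

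Genes changed alike in the 3D and animal libraries answer which differences from 2D both models share. Higher in both were 412 genes and lower in both 142, against 201 and 70.6 from the product of the call rates, and 131 genes were called in opposite directions. The largest shared rises were in IGFBP5, an insulin-like growth factor binding protein (15.6-fold in 3D and 79.6-fold in animal libraries), the copper carrier CP (16.5-fold and 38.2-fold), LCN2 (57.0-fold and 22.1-fold), TMEM45A (12.5-fold and 11.1-fold) and TFF3 (10.2-fold and 11.9-fold). The largest shared falls were in the water and glycerol channel AQP3 (3.48-fold and 8.27-fold), SLC6A20 (3.4-fold and 6.40-fold), NAMPT, an enzyme of NAD synthesis (3.4-fold and 4.07-fold), NAV3 (4.13-fold and 3.72-fold) and POP1 (3.36-fold and 3.85-fold). In 3D, NAMPT had a log2 fold change of -0.45 after the correction (adjusted p = 0.171) and -1.12 without 3D replicates 1 and 2 (adjusted p = 0.000581). Over the alternatives the adjusted p reached 0.0558 for AQP3 and 0.0504 for SLC6A20 in 3D, and 0.0586 for TMEM45A in the animal libraries. Both comparisons use the same 2D libraries. In 20 simulations without any difference the correlation across genes was 0.496, and the real value was 0.229. The covariance was 0.298 against a simulated 0.0930, and the simulations gave 0 shared genes in either direction. They drew every library with the same spread per gene. The SD of log2 differences between real replicates was 0.247 to 0.261 in 2D, 0.692 to 1.54 in 3D and 0.419 to 0.597 in animal libraries. The simulated correlation and covariance therefore cannot say how much the shared 2D libraries bring. The shared counts were 134 to 158 higher and 26 to 32 lower on leaving out any 2D library, 272 and 61 with replicate number as a block, 519 and 894 after the correction, and 1451 and 1655 without 3D replicates 1 and 2.

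The comparison of animal with 3D libraries asks how the models differ from each other. Rises in the animal libraries, hepatocyte genes included, may hold host reads here too, which was not tested. In the animal libraries glycolysis genes were lower in 14 of 17 (14 adjusted over the list alone, median -1.51, -0.92 without 3D replicates 1 and 2), cholesterol synthesis genes in 14 of 23 (14 adjusted over the list alone, median -1.03, -0.95 without them) and hypoxia genes in 9 of 22 (9 adjusted over the list alone, median -0.85, -1.29 without them). The glycolytic enzymes ALDOA and PGK1 were 5.81-fold and 3.66-fold lower, NSDHL 3.71-fold, ANGPTL4 13.3-fold at 52.9 ± 25.6 against 705 ± 155 CPM, and the glucose transporter SLC2A1 4.01-fold. Camera adjusted p-values were 1.80e-07, 0.00144 and 0.00348, and with an estimated correlation the adjusted p was 0.429, 0.429 and 0.593. Hepatocyte genes were higher in 11 of 21 with 1 lower (11 and 2 adjusted over the list alone, median 2.08, 1.95 without the 2 libraries; adjusted p = 0.000910, 0.305 with an estimated correlation). ALB was 62.4-fold and TF 69.7-fold higher.

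Of 10 AHR target genes 5 were lower and 1 higher in animal than in 3D libraries (5 and 1 adjusted over the list alone, median -0.99, -1.27 without 3D replicates 1 and 2; adjusted p = 0.0251, 0.429 with an estimated correlation). CYP1A1 had 3 reads against 704 (ratio 256, 95% interval 87.2 to 1244), CYP1B1 measured 2.60 ± 0.492 against 194 ± 194 CPM and ALDH3A1 was 8.76-fold lower. ATF4 and stress response genes were lower in 8 of 16 (9 adjusted over the list alone, median -0.86, -0.42 without the 2 libraries; adjusted p = 0.00711, 0.547 with an estimated correlation). DDIT4 and SESN2, both inhibitors of mTORC1, were 4.64-fold and 5.12-fold lower. Chaperones were higher in 9 of 25 with 1 lower (9 and 1 adjusted over the list alone, median 0.31, 0.95 without them; adjusted p = 0.0188, 0.593 with an estimated correlation), with HSPH1 at 185 ± 114 against 30.8 ± 9.36 CPM and HSPD1 at 2.91-fold. G2 and M phase genes were higher in 10 of 20 with 1 lower (12 and 2 adjusted over the list alone, median 0.55, 0.77 without them; adjusted p = 0.0247, 0.547 with an estimated correlation), and replication genes in 8 of 20 (8 adjusted over the list alone, median 0.53, 1.19 without them; adjusted p = 0.0235, 0.593 with an estimated correlation). MKI67 was 2.15-fold and RFC4 2.66-fold higher.

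Fibroblast and pericyte markers were higher in 8 of 13 with 3 lower (8 and 3 adjusted over the list alone, median 3.26, 2.26 without the 2 libraries; adjusted p = 0.0289, 0.547 with an estimated correlation). COL1A1 was 162-fold higher and COL6A2 4.22-fold lower. Immediate early genes were lower in 7 of 15 (7 adjusted over the list alone; adjusted p = 0.00711, 0.547 with an estimated correlation), with a median of -0.79 in the main fit, -0.47 without 3D replicates 1 and 2 and 0.04 after correction; the RNA-decay factor ZFP36 was 4.05-fold lower. Ribosomal proteins were lower in 17 of 28 (17 adjusted over the list alone, median -0.91, -0.13 without 3D replicates 1 and 2; adjusted p = 0.00174, 0.593 with an estimated correlation), with RPS20 3.33-fold lower. Oxidative phosphorylation genes were lower in 10 of 22 with 1 higher (11 and 1 adjusted over the list alone, median -0.77, 0.08 without them; adjusted p = 0.00667, 0.593 with an estimated correlation), with SDHA 2.51-fold lower. Tryptophan catabolism genes had a median of 0.20, and 0.69 without the 2 libraries (adjusted p = 0.489; 4 of 16 higher and 3 lower, also adjusted over the list alone), with TDO2 6.66-fold higher, MAOB, a monoamine oxidase, 2.67-fold lower, and HAAO at 0 reads in 3D and at least 4.68-fold higher.

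The largest rises from 3D to animal libraries were in ACSS3, LIN7A and ADH1C, with 1, 2 and 2 reads over the 3D libraries (ratios of 1053, 554 and 506, 95% intervals 189 to 41635, 153 to 4581 and 140 to 4179), COL1A1, PMEPA1 (106-fold) and TF. The largest falls were in the calcium channel subunit CACNG7 (228-fold), CYP1B1, the transcription factors SOX18 (72.0-fold) and PRRX2 (67.8-fold), GAMT (59.1-fold) and NRXN2 (49.1-fold). Without 3D replicates 1 and 2 the log2 fold changes of CACNG7, CYP1B1, SOX18, PRRX2, GAMT and NRXN2 were -7.43, -7.31, -5.34, -4.63, -4.11 and -4.44, against -7.83, -6.22, -6.17, -6.08, -5.89 and -5.62 with them. In all, 2406 genes were higher and 2961 lower among 12925, and 50.2% did not overlap. The counts were 996 and 1750 with only these 2 groups, 5596 and 4536 without 3D replicate 3 and 3347 and 3058 without 3D replicates 1 and 2. They were 1377 and 1984 without 3D replicate 1, and between 1537 and 1556 and between 1943 and 2042 on leaving out any animal library. The other 16 lists had camera adjusted p-values from 0.0661 to 0.896. Without 3D replicate 3, 0 lists passed as higher and 4 as lower, against 5 and 8 in the main fit. The camera call of every higher list above, hepatocyte genes included, thus rests on that library. The levels of single genes need not: with the 15 libraries scaled together, ALB measured 4.42, 2.04 and 1.66 CPM in 3D replicates 1, 2 and 3. It measured 116, 90.9 and 283 CPM in the animal libraries. The median, the mean and the direction in camera differed in sign for YAP targets, integrins, epithelial junctions, interferon genes and endothelial markers.

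Heat against control in 3D asks how cells in the 3D model respond to heating. TRIM31, a ubiquitin ligase, was 23.3-fold higher at 29.5 ± 5.80 against 1.26 ± 0.104 CPM (adjusted p = 0.0192), and MAOA, a monoamine oxidase, was 5.57-fold lower at 27.4 ± 0.605 against 153 ± 5.64 CPM (adjusted p = 0.0489). Heat shock chaperones had a median log2 fold change of 1.66 over 25 genes, with 0 called over all genes and 11 higher adjusted over the list alone (camera adjusted p = 4.62e-08, 0.364 with an estimated correlation; median 1.31 without heat replicate 1). HSPA6, an inducible Hsp70, measured 1157 ± 1061 against 1.14 ± 0.274 CPM (adjusted p = 0.0699), CRYAB, a small heat shock protein, 832 ± 1050 against 4.28 ± 0.60 (0.0875), and HSPA1B, which shares reads with the near-identical HSPA1A, 12238 ± 10067 against 298 ± 7.70 (0.0952). The chaperone median over the controls was 2.25, 0.15 and 1.93 in heat replicates 1, 2 and 3. Members went both ways in heat replicate 2, so its median does not mean that no chaperone rose. On the log2 scale over the controls, HSPA6 lay at 6.45, CRYAB at 4.90 and HSPA1B at 2.00 there. HSPA8, singled out after its value was seen, lay at -1.71.

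**Figure D4:**
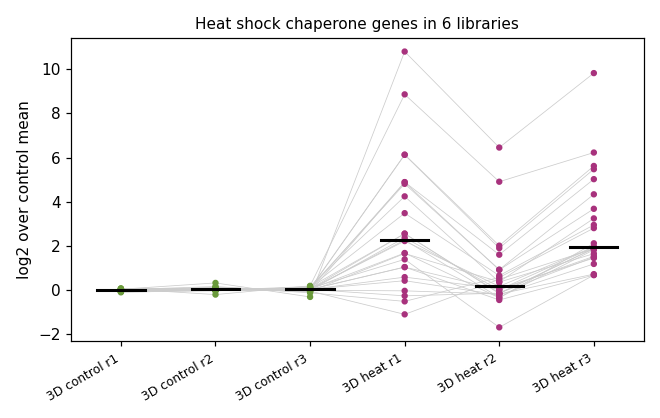
Log2 level of 25 chaperone genes over the mean of the 3D controls (y axis) in the 3 control and 3 heated libraries; points are genes, grey lines join a gene and black bars are medians. Medians are 2.25, 0.15 and 1.93 in heat replicates 1, 2 and 3.

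In each other list that passed camera, 0 members were called over all genes. Immediate early genes had a median of 1.33 (8 of 15 higher adjusted over the list alone; camera adjusted p = 0.000410, 0.424 with an estimated correlation; 0.92 without heat replicate 1). The transcription factors FOSB and EGR1 measured 370 ± 357 and 408 ± 294 CPM against 3.23 ± 0.528 and 47.3 ± 13.1. NF-kB and inflammatory genes had a median of 0.75 (4 of 18 higher adjusted over the list alone; adjusted p = 0.00254, 0.165 with an estimated correlation; 0.83 without it), with the NF-kB subunit NFKB2 at 142 ± 41.2 against 55.5 ± 3.06 CPM. Ribosomal proteins had a median of 1.48 (0 of 28 adjusted over the list alone; adjusted p = 0.00254, 0.738 with an estimated correlation), and of -0.01 without heat replicate 1; RPLP1 measured 1625 ± 2119.9 against 386 ± 8.30 CPM.

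Lipid synthesis lists were lower as sets with heat: fatty acid synthesis with a median of -0.79 (7 of 13 lower adjusted over the list alone; adjusted p = 2.65e-05, 0.169 with an estimated correlation; -0.83 without heat replicate 1) and cholesterol synthesis with -0.70 (5 of 23; adjusted p = 3.29e-05, 0.311 with an estimated correlation; -0.56 without it). The desaturases SCD and FADS2 measured 322 ± 84.5 against 1160 ± 98.6 CPM and 65.0 ± 25.7 against 296 ± 59.4. The cyclase LSS, of cholesterol synthesis, measured 32.3 ± 11.1 against 117 ± 19.9. Adhesion lists were lower too: integrins and basement membrane with -0.86 (5 of 20 lower adjusted over the list alone; adjusted p = 0.000293, 0.165 with an estimated correlation; -0.70 without it) and epithelial junctions with -0.53 (3 of 13; adjusted p = 0.00231, 0.165 with an estimated correlation; -0.92 without it). LAMA3, a laminin chain, measured 77.1 ± 25.4 against 570 ± 14.2 CPM, and CLDN1, a tight junction protein, 5.04 ± 0.212 against 22.8 ± 1.34.

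Hypoxia genes had a median of -0.68 (1 of 22 lower adjusted over the list alone; adjusted p = 1.66e-05, 0.364 with an estimated correlation; -0.50 without heat replicate 1), with the collagen cross-linking enzyme LOX at 1.57 ± 1.37 against 27.4 ± 3.22 CPM. Glycolysis had a median of -0.45 (0 of 17 adjusted over the list alone; adjusted p = 0.00390, 0.494 with an estimated correlation; -0.89 without it), with LDHA at 799 ± 201 against 1860 ± 28.0 CPM. G2 and M phase had -0.65 (2 of 20; adjusted p = 0.000390, 0.165 with an estimated correlation; -0.58 without it), replication -0.29 (3 of 20; adjusted p = 0.0463, 0.333 with an estimated correlation; -0.27 without it), and hepatocyte genes -0.71 (2 of 18; adjusted p = 0.00798, 0.333 with an estimated correlation; -0.84 without it), these counts being lower genes adjusted over the list alone. MKI67 measured 138 ± 33.5 against 305 ± 17.8 CPM, the nucleotide reductase subunit RRM2 36.0 ± 1.72 against 93.8 ± 7.84, and APOB, the main protein of liver lipoproteins, 3.20 ± 0.625 against 17.6 ± 1.47. AHR targets had a median of -0.19 (0 of 10 adjusted over the list alone; adjusted p = 0.0857), and of -0.42 without heat replicate 1 (adjusted p = 0.0482), with CYP1A1 at 3.94 ± 2.88 against 16.0 ± 1.48 CPM. Tryptophan catabolism had -0.26 (adjusted p = 0.166; 1 of 14 lower over all genes, 1 higher and 2 lower adjusted over the list alone), with KYAT3 at 6.52 ± 1.39 against 19.9 ± 1.46 CPM. Without heat replicate 1 its median was -0.62 (adjusted p = 0.0481).

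In all, 1 gene was higher and 2 lower with heat among 12627 in edgeR: TRIM31, MAOA and the focal adhesion gene TNS4, which was singled out after its value was seen. At an unadjusted p below 0.05 there were 2628 genes, and 36.6% did not overlap. DESeq2 called 851 and 690, the fit with replicate number as a block 22 and 8, the corrected fit 683 and 784, the fit with heat replicate 1 left out 1795 and 1896, and that with heat replicate 2 left out 585 and 460. Without heat replicate 3, or without any one control, there were 0 and 0. The other 16 lists had camera adjusted p-values from 0.0857 to 0.766. Here YAP targets, NRF2 targets and fibroblast markers differed in sign between median, mean and direction in camera.

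Log2 fold changes of 3D against 2D and of heat against control shared no libraries. Across 12472 genes, which are not independent replicates, they had a Pearson correlation of 0.159 and a Spearman correlation of 0.197. The Pearson value was -0.20 without heat replicate 1 and -0.05 after the correction. TRIM31 was higher, and MAOA and TNS4 lower, in both comparisons.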

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

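No group has more than 3 libraries, so no library was tested as an outlier by a rule, and the design holds no contrast repeated in a second group. The tests below of the libraries that stand apart, of heat replicate 2 and of the fibroblast markers were all chosen after the results were seen; only the splits were planned.

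Each comparison sets 3 libraries against 3, which makes 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many called genes as the real one. The real splits called 4247 genes for 3D against 2D, 1555 for animal against 2D, 5367 for animal against 3D and 3 for heat against control, and the highest count among the other splits was 0 in each.

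3D replicates 1 and 2 and heat replicate 1 depart from their group mates along GC content and transcript length. Fewer reads are argued against, since their lowest total was 1.27 times the lowest of the other 12, which show no such trend. Whether the 3D model or heat acted in every library of its group cannot be tested on group mates, since the 3 libraries were singled out for differing from them. The 3D controls hold the same model in the second experiment. They reached a rank correlation with GC content of at most 0.226, against at least 0.593 in the 3 libraries. This argues against the 3D model by itself and says nothing on heat. Whether GC content and length bias is the whole cause cannot be told. The departures of 3D and heat libraries correlated across genes with r = 0.820, and with 0.659 (95% interval 0.646 to 0.671) after a GC and length surface was taken out. The interval resamples genes, which are not independent, and does not measure the spread between libraries. The surface used each gene's longest transcript (7062 bases for RPS29), which need not be the one expressed. Errors in these values are the same in both experiments and can leave such a correlation. Also open, and untested, is a difference in RNA quality or library preparation, or a state of the cells in these cultures only.

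Chaperones were lower in heat replicate 2 than in heat replicates 1 and 3, by 1.94 on the log2 scale in the median over 25 genes. A swap with a control library is argued against, since no control departed from the other controls by more than 0.0357, and GC content and length bias is too, since the gap to heat replicate 3 was 2.05 before and 2.03 after correction (quartiles 1.42 to 2.71). A share of unheated cells or RNA in heat replicate 2 stays open as part of the cause. In heat replicate 2, 93 other genes raised at least 4-fold in heat replicates 1 and 3 reached a median fraction of 0.109 of their rise (quartiles 0.0578 to 0.193). For 8 chaperones raised as much it was 0.0576 (0.0469 to 0.0665). The rule for this test was changed after its values were seen: a first version compared the medians of raised genes and a second only the 493 lowered genes, whose median fraction was 0.654 (0.429 to 0.833), and either would have excluded a share of unheated cells. The version kept asks for both lower quartiles to lie above the chaperones' upper quartile, which the raised genes do not meet, and a milder or differently timed heating was not tested. A share of unheated cells alone would give raised and lowered genes the same fraction. The lowered genes, at 0.654 against 0.0576 for the chaperones, argue against it as the only cause.

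Fibroblast markers were higher as a list in the animal libraries than in 2D, with a median log2 fold change of 1.77 over 13 genes. Of these, 7 were called higher, among them COL1A1, and 1 lower. The collagens COL6A1 and COL6A2 did not rise, at 802 and 329 CPM against 811 and 408 in 2D. GC content and length bias is argued against, since the median was 1.53 after correction. Reads from host cells may contribute and stay open, since how well reads of the unnamed host map to each human gene is not known: over the 30 macrophage and endothelial markers the median gain over 2D was 0.378 CPM, CD68, CD74, ITGAM, KDR, LYZ, CD163 and ENG gained more than 1 CPM (CD74 measured 21.8 against 1.62), and C1QA, C1QB, C1QC, TYROBP and EMCN had 0 reads. In the 3D libraries CD68, ITGAM and ENG measured 427, 10.3 and 2.70 CPM, against 155, 11.6 and 2.72 in the animal libraries. Their levels are thus not particular to the animal model. CD74, KDR, LYZ and CD163 measured 6.34, 0.745, 0.0459 and 0.266 CPM in 3D, against 21.8, 8.05, 5.82 and 4.91. An earlier version of this test looked at 10 of the 30 markers, picked after the data were seen, and left out those that rose most. A change that 3D growth alone brings stays open over the whole list. Its median in 3D against 2D was -0.41, with a lower quartile of the members' differences of -0.27. Without 3D replicates 1 and 2 the list's median was 0.67, the opposite sign. The 7 members called higher had medians of 5.64 in animal and -0.50 in 3D libraries (quartiles of the difference 4.44 to 6.71), but they were picked by the pattern itself. COL1A1 measured 119.7, 246.9 and 60.3 CPM in the 3 animal libraries. LUM, COL6A1, COL6A2 and COL6A3 lay above 50 CPM in 2D already, and COL6A3 fell from 64.4 to 6.89 CPM in the animal libraries.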

How the results depend on the processing

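The GC and length correction, the fits without 3D replicates 1 and 2 and without those and heat replicate 1, and the leave-one-out correlations were chosen after the data had been seen; the other alternatives were planned. Of the named genes called in edgeR, 60 of 77 in 3D against 2D, 54 of 71 in animal against 2D, 56 of 67 in animal against 3D and 0 of 2 with heat kept call and direction under every alternative run for them. Among values of single genes and lists, 4019 kept direction and side of the threshold, 205 newly passed it, 133 no longer did and 11 reversed. Among counts and the correlation, 177 stayed within 1.5 times or 1 spread, 33 were larger, 64 smaller, 1 moved and 3 reversed. Where no reason is named, the cause was not tested.

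With DESeq2, 1007 genes were lower in animal against 2D, 851 were higher and 690 lower with heat, and 622 and 312 were shared by 3D and animal libraries. With median-ratio scaling 0 genes were lower with heat, and with no filter 1 was. With replicate number as a block, 322 genes were lower in animal against 2D, 22 were higher and 8 lower with heat, and 272 and 61 were shared. With only the 2 groups compared in the fit, which changes the pooled spread, the counts were 1695 and 798 for 3D against 2D, 3751 and 3538 for animal against 2D, 996 and 1750 for animal against 3D, and 696 and 393 shared. A fold threshold of 2, which removes smaller changes by construction, left 1085 genes lower in 3D and 60 lower in both. With an estimated correlation, 4 lists were higher and 0 lower in animal against 2D, and 0 were higher and 0 lower in each of the other 3 comparisons. Some lists passed camera but not fry. With heat these were (fry adjusted p) chaperones and immediate early genes (0.147), ribosomal proteins (0.521), glycolysis (0.162), hypoxia (0.0927) and hepatocyte genes (0.0526). In animal against 2D they were replication (0.0890) and immediate early genes (0.0519). Oxidative phosphorylation was at 0.0902 in 3D against 2D and 0.0626 in animal against 3D, where ribosomal proteins were at 0.0504. Every other list that passed camera passed fry.

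After the GC and length correction 2700 genes were lower in 3D against 2D, 1707 were higher and 2332 lower in animal against 2D, 683 and 784 with heat, and 894 were lower in both models. Without 3D replicates 1 and 2, 3205 genes were lower in 3D, and 1451 and 1655 were shared. With the correction, log2 fold changes reversed to 0.42 for SP1, 0.82 for KYNU and 0.15 for NDUFS1 in 3D against 2D, and to -0.36 for SP1, -0.82 for KYNU, -0.37 for NDUFS1, 0.0197 for PPP1R15A, 0.0834 for IER2 and 0.0423 for RPS15 in animal against 3D. Without 3D replicates 1 and 2, SP1 reversed to 0.37 and -0.36, while the other 5 genes kept their sign. The correlation of 3D with heat fold changes reversed to -0.0510 after the correction and to -0.09 without the 3 libraries, a setting under which 14 lists were lower with heat.

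Leaving out 1 library gave 1132 to 4560 genes higher and 663 to 4933 lower in 3D against 2D, 446 to 768 and 199 to 386 in animal against 2D, 1377 to 5596 and 1943 to 4536 in animal against 3D, and 0 to 1795 and 0 to 1896 with heat. The highest counts came without 3D replicate 3 in the comparisons of 3D, without animal replicate 2 in animal against 2D, and without heat replicate 1 with heat. Shared genes ranged from 134 to 1074 higher and 26 to 756 lower. Lists lower in 3D against 2D ranged from 2 to 3, lists in animal against 3D from 0 to 5 higher and 4 to 9 lower (0 and 4 without 3D replicate 3), and lists lower with heat from 6 to 14 (14 without heat replicate 1). The correlation ranged from -0.20 without heat replicate 1 to 0.35 without heat replicate 3.

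The median log2 fold change over all genes was 0.03, 0.03, 0.10 and 0.10 in the 4 comparisons, 0.11 for 3D against 2D with median-ratio scaling, and 0.10 and 0.21 for animal against 2D and animal against 3D with upper-quartile scaling. Medians of lists are relative to these. In simulated data edgeR recovered 59% of 4-fold and 2% of 2-fold changes in 3D against 2D, and 28% and 1% with heat. Most 2-fold changes in both, and most 4-fold changes with heat, thus go uncalled at this spread, and depth was not varied. With the GC and length trends of the real libraries added, the main fit recovered 44% of 4-fold changes in 3D against 2D, 0% in animal against 2D and 0% with heat. The corrected fit recovered 59% in animal against 2D and 20% with heat at the same library sizes. The simulated dispersions came from real libraries that already carry these trends, so their spread may be counted again. The real main fit called 1555 genes in animal against 2D. The 0% values therefore cannot say how many real changes go uncalled.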

Other observations

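All values here were chosen after the data had been seen. The 3D and 3D control libraries carry the same model in different experiments. IL4I1 was higher in the 3D libraries than in the 3D controls, with a log2 fold change of 3.52 (adjusted p = 0.00629 in edgeR over the 15 libraries) and of 2.57 after the GC and length correction (adjusted p = 0.00491). Against 2D, IL4I1 in the 3D controls had a log2 fold change of 1.24 (adjusted p = 0.352). In that fit 123 genes were higher and 1 lower in the 3D controls than in 2D, and 164 and 172 in the 3D libraries than in the controls. The experiments were sequenced in separate rounds, so batch and group cannot be told apart in these values.

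The mean correlation across genes with the 3D controls was 0.976 to 0.979 for the 2D libraries, 0.975 for 3D replicate 3, and 0.917 and 0.859 for 3D replicates 1 and 2. It was 0.862, 0.965 and 0.923 for heat replicates 1, 2 and 3. Some genes were lower in the libraries that stand apart, in both experiments and beyond the fitted trend with GC content and length, which rests on each gene's longest transcript. Among them were GOLGA8A and GOLGA8B, which are close copies of each other, NKTR, CLK2, LENG8 and MYSM1. PSMA5, POMP, SNRPF, ATOX1 and RPS29, which encode proteasome, spliceosome, copper-carrier and ribosomal proteins, were higher there.

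By chromosome, 9 of 23 passed camera in 3D against 2D and 0 after the GC and length correction. In animal against 3D 10 passed before and 1 after it, in animal against 2D 0 and 1, and with heat 1 and 0. The chromosome that passed after it was X in both animal comparisons, with medians of -0.28 against 3D and -0.36 against 2D (adjusted p = 0.0138 and 0.0219), from -0.09 and -0.20 before. In 3D against 2D the median of chromosome 19 was 0.81 before and -0.08 after it, and that of chromosome 18 was -0.56 and -0.22. With an estimated correlation 0 chromosomes passed in any of the 4 comparisons.

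MAGEC1, a cancer-testis antigen gene, had 149, 113 and 129 reads in the 2D libraries and 0, 0 and 1 in the animal libraries. Its neighbour MAGEC2, with the 15 libraries scaled together, measured 3.54 ± 0.222 CPM in 2D and 67.7 ± 21.5 in the animal libraries.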
